A study of Mus musculus with 25 samples.

How the data were processed

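Small RNA libraries were made from the blood of male C57BL/6 mice, an inbred laboratory strain, at 5 ages of 2, 9, 15, 24 and 30 months. Each age had 5 libraries, each from a separately numbered animal, so 25 libraries entered the comparisons and n is 5 for every age. The libraries were made with the TruSeq small RNA kit, per the labels' protocols. The authors deposited 1 table of raw counts, in which each value is the number of reads assigned to a microRNA precursor (hairpin) in a library. The table does not separate the 2 arms of a hairpin. The tools bcl2fastq 1.8.4, Trimmomatic 0.36 and SAMtools 1.3.1-9 are named, without their roles, per the submitters' processing notes. The aligner, the read counter, the microRNA release, the genome build and the use of strand are not given in the sources used here. Counts differed in total between libraries and were whole numbers, so they were taken as unnormalised.

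The table had 1193 precursors, of which 328 were at 0 in every library and 865 had at least 1 count. The total count per library ran from 4.884 to 24.25 M with a median of 15.39 M. A floor of 3 counts corresponds to 0.614 CPM (counts scaled by library size) in the smallest library and 0.124 CPM in the largest. The kit adds no molecular identifiers, so floors cover counting error only. Replicates were compared before averaging. Over the 50 pairs of libraries of the same age, the smallest chi-square per degree of freedom was 126.8, so no pair of libraries matched within sampling noise. Replicate numbers follow the order of the deposited samples and pair no animals across ages. The column names carry sequencing lanes from 3 to 8, and the 6 lanes were spread unevenly over the ages. Lane 3 held 1 library each of 9, 15 and 24 months and none of 2 or 30 months, lane 4 held none of 30 months, and lane 6 held 2 of 30 months. The column names also give an index sequence, which differs in every library. In alphabetical order the index sequences follow the ages, except those of 30 months replicates 4 and 5. Index and age therefore cannot be told apart, and an effect of index was not tested.

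Copies of one microRNA held near-identical counts, as would follow if reads that fit several hairpins were counted in each or divided among them. Which rule was used is not given in the sources used here. Among the precursors, 14 groups had counts within 0.2 log2 units in every library at a mean of at least 20 counts, and 23 pairs of hairpins overlapped in the genome. Without knowledge of strand, reads of a hairpin and its antisense partner cannot be told apart, as for mir-451a and mir-451b, mir-486a and mir-486b, mir-30e and mir-30f, mir-126a and mir-126b, and mir-24-2 and mir-3074-2. Values of such members, including let-7f-1 and let-7f-2 and mir-16-1 and mir-16-2, are uncertain as to which hairpin the reads came from. The 338 tested precursors made up 318 read units when such groups were counted once. Positions come from a RefSeq gene table of the mouse assembly GRCm38.p6, which matched 1182 of the 1193 precursors by name, and from GENCODE vM21 on the same assembly, which placed 1178 of them at the same coordinates. These are positions of the named hairpins in that assembly, not in the build the authors used. Hairpins are called intergenic where no gene other than a microRNA lay across them on the same strand, and the opposite strand was not examined.

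Differential abundance was tested with the quasi-likelihood F test of edgeR 4.0.16 in R 4.3.3, with trimmed mean of M-values (TMM) factors, the default expression filter by age and robust dispersion estimates. All 25 libraries shared 1 fit. The filter kept 338 precursors, which held at least 99.992% of the counts of every library. The common biological coefficient of variation was 28.1%. Comparisons were any age, 9, 15, 24 and 30 months each against 2 months, the consecutive pairs 15 against 9, 24 against 15 and 30 against 24 months, and a linear trend in months. P-values were adjusted by the Benjamini-Hochberg method over the 338 precursors of each comparison, with a threshold of 0.05. Every adjusted p of a precursor below comes from this edgeR test, all tests are two-sided unless stated, and log2 changes have the younger age as the base. CPM values use TMM-scaled library sizes and are given as mean ± SD.

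Precursors named in the text follow a rule set before the data were examined. For 30 against 2 months it took up to 10 changed precursors in each direction with the largest fold, among those with a mean of at least 10 CPM at either age. For every other pair of ages it took up to 4 in each direction, and for the trend up to 8 in each direction by adjusted p. It added the 10 most abundant precursors, up to 3 members of each tested list by adjusted p, and mir-451a and mir-23a. In all it named 67 precursors. Precursors named outside this rule are marked as chosen after their values were seen, apart from some list members. These are mir-183, mir-199a-1, mir-150, mir-205, mir-200c, mir-467d, mir-155, mir-21a, mir-24-1 and mir-222. The list results name them without that mark, outside the rule, and some average under 10 CPM. Also set before the data were examined were 25 lists of precursors, of which 22 had the minimum of 3 tested members. They held erythroid, lymphoid, myeloid, platelet and endothelial, liver, muscle, epithelial, brain, smooth muscle and fibroblast, pancreas, inflammation and p53 or senescence microRNAs. The others were the miR-17-92, miR-106a-363, miR-106b-25, miR-15/16, let-7, miR-29, miR-30, miR-181, miR-183-96-182, miR-99/125 and miR-221-222 clusters or families and the imprinted Dlk1-Dio3 and Sfmbt2 clusters. Lists overlap: 7 of 9 tested inflammation members, 4 of 8 myeloid members, 8 of 12 lymphoid members and 5 of 9 erythroid members were also in another list. List tests used camera of limma 3.58.1 with a preset correlation of 0.01, repeated with an estimated correlation, and fry. Their p-values were adjusted over the 22 lists of a comparison.

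Measures of library composition were the total count, the shares of the most abundant precursor, of the 10 most abundant and of the erythroid list, the log2 ratio of mir-451a to mir-23a counts, and the number of precursors detected after thinning to 4.884 M counts. The ratio is known as an index of hemolysis (burst red cells) and was not tested as a measure of red cell content in whole blood. It was planned on the mature miR-23a-3p arm and computed on the precursors, because the table has no arms. Correlations with age used 1e+05 permutations, for which 1e-05 is the smallest p, and were also computed within lanes. Comparisons of 30 with 2 months used all 252 assignments of 5 against 5 libraries, which allow a smallest exact p of 0.0079. The spread of a library within its age was the root mean square of its log2 CPM deviations from the age mean. It was taken over the 87 precursors of at least 100 CPM.

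The scripts were tested on simulated counts drawn from the means, totals and dispersions of these libraries, with 200 precursors seeded as changed. In the simulated 30 against 2 months comparison 340 precursors were tested. There edgeR recovered 80.5% of the 41 tested 2-fold changes and 97.1% of the 35 tested 4-fold changes, and 6 of its 73 calls were false (8.22%). A simulated trend of 1 log2 unit over 30 months was recovered for 15 of 26 precursors with 1 false call. A list raised 1.5-fold passed with an adjusted p of 6.89e-11, and 0 of the other lists passed. Alternatives planned before the data were examined were relative log expression, total count and upper quartile scaling, TMM without the 10 most abundant precursors and the erythroid list, no filter, a filter of 10 CPM, DESeq2 1.42.0, limma-voom, fits of the 10 compared libraries alone, each library left out in turn, and other forms of the trend. Chosen after seeing the data were lane as a covariate, leaving out the 3 libraries of lane 3, leaving out the libraries under 6 M counts, thinning to the smallest total, 1 precursor per read unit, and an offset for hairpin GC content, which was known for 335 of the 338 tested precursors. Tables and plots were made with Python 3.11.15, pandas 2.3.3 and matplotlib 3.10.9.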

Results

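MicroRNA precursors were counted in the blood of male C57BL/6 mice at 5 ages, from young adulthood at 2 months through 9, 15 and 24 months to old age at 30 months, to ask how blood microRNAs differ with age. Each age had 5 libraries. The mean total count was 18.84 ± 2.81 M (mega) counts at 2 months, 16.15 ± 2.46 M at 9 months, 18.2 ± 4.36 M at 15 months, 14.32 ± 5.98 M at 24 months and 9.888 ± 2.71 M at 30 months (SD, n = 5 each). Single libraries ranged from 4.884 M (24 months replicate 4) to 24.25 M (15 months replicate 3). Libraries of 30 months, with the fewest counts, give the least precise values of rare precursors.

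MicroRNAs of red cells took most of the counts at every age. The erythroid list held 71.6% ± 0.740 of the counts at 2 months and 68.5% ± 2.76 at 30 months (SD, n = 5 each). If reads of mir-486 were counted for both mir-486a and mir-486b, these shares hold them more than once. The most abundant precursors were mir-486a, which lies in an intron of Ank1 on chromosome 8 (23142555 to 23142682) and whose counts cannot be separated from those of mir-486b, then mir-451a, mir-22, mir-92a-1, mir-25, mir-16-1 and mir-191. At 30 against 2 months none of these passed the edgeR test, with the smallest adjusted p at 0.234 for mir-16-1, which shares its reads with mir-16-2. Their log2 changes were −0.30 (SE 0.18) for mir-486a, −0.21 (SE 0.14) for mir-451a, −0.03 (SE 0.13) for mir-22, 0.04 (SE 0.10) for mir-92a-1, 0.06 (SE 0.11) for mir-25, −0.54 (SE 0.29) for mir-16-1 and 0.02 (SE 0.17) for mir-191. The values for mir-451a and mir-22 lie on the other side of 0 when libraries are scaled by their totals, at up to 0.03 and 0.23.

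Differences between any of the 5 ages were found for 27 of the tested precursors, led by mir-296, mir-203, mir-298, mir-223, mir-23a, mir-211 and mir-10a. Of these, mir-298 and mir-211 have under 10 CPM at every age and were chosen after their values were seen. The linear trend with age was past the threshold for 67 precursors, 36 higher and 31 lower with age, but 80 and 9 with library totals and 38 and 18 with upper quartile factors, so the number of falls depends on the scaling. Among those with a mean of at least 10 CPM at some age, the steepest rises were those of mir-203, a microRNA known from skin epithelium, at 0.59 log2 units per 10 months (SE 0.05, adjusted p = 3.87e-10), mir-182 at 0.48 (SE 0.10), and mir-223, known from neutrophils and monocytes, at 0.43 (SE 0.07). Smaller rises were found for mir-10a at 0.35 (SE 0.07), mir-23a at 0.32 (SE 0.06), mir-28a at 0.29 (SE 0.06) and mir-24-2 at 0.15 (SE 0.03). mir-3074-2 overlaps mir-24-2 on the opposite strand and cannot be told apart from it. The steepest fall was that of mir-296, at −1.35 log2 units per 10 months (SE 0.11, adjusted p = 3.87e-10). It was followed by mir-32 at −0.52 (SE 0.14), mir-144 of red cells at −0.49 (SE 0.11), let-7f-1 at −0.46 (SE 0.11), mir-101a at −0.45 (SE 0.14), mir-98 at −0.44 (SE 0.10), let-7g at −0.39 (SE 0.11). A shallower fall was that of mir-8114, in an exon of Glul, at −0.17 (SE 0.05). Without the 2-month group, in a fit with 5 fewer libraries, 9 precursors passed, 6 higher and 3 lower, all among the 67, and mir-203, mir-28a and mir-296 were the ones named here. The slopes per 10 months were then 0.60 for mir-203, −0.45 for mir-98 and −0.46 for let-7f-1, near those given, but −0.80 for mir-296, 0.32 for mir-223, 0.23 for mir-23a and 0.18 for mir-10a. The call of mir-8114 ended in 21 of 41 alternatives, with slopes down to −0.0062 log2 units per month, and that of mir-101a in 7, with adjusted p up to 0.252.

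By camera, the lists with a trend were the same 3 that stand out at 30 months. Myeloid microRNAs rose with age (camera adjusted p = 0.00118, but adjusted p = 0.0750 with an estimated correlation), with 6 of 8 members up over all precursors and 6 adjusted over the list alone. Inflammation microRNAs rose (adjusted p = 0.0120, but adjusted p = 0.0750 with an estimated correlation), with 5 of 9 and 6. let-7 microRNAs fell (adjusted p = 0.00234, but adjusted p = 0.896 with an estimated correlation), with 6 of 13 and 7. By fry let-7 did not pass (adjusted p = 0.0531), while the miR-17-92 list fell (adjusted p = 0.0438, camera adjusted p = 0.478), with 2 of 8 members down by either adjustment.

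**Figure D1:**
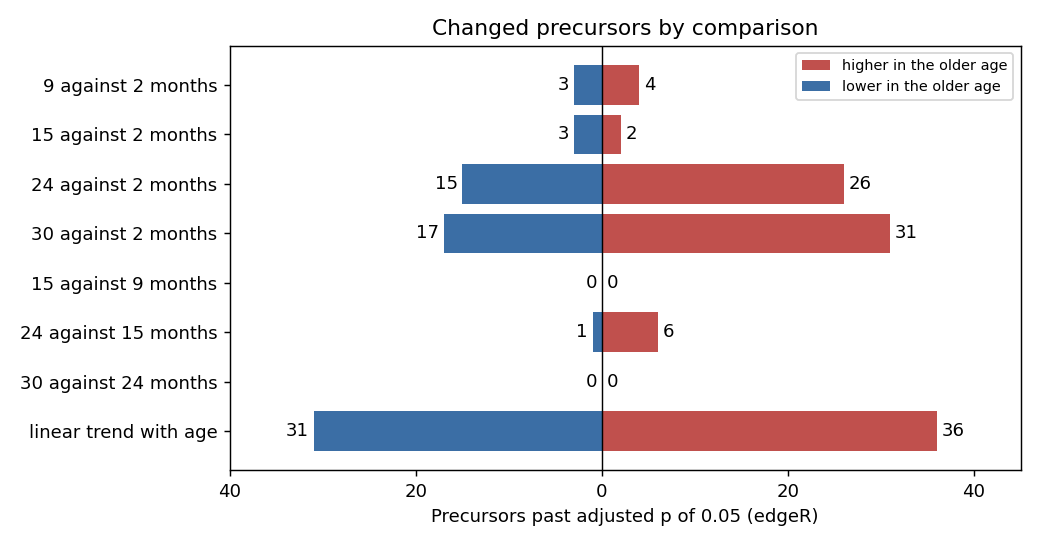
Number of precursors past an adjusted p of 0.05 (horizontal axis) in each comparison of ages and in the linear trend (vertical axis), with red bars to the right for precursors higher in the older age and blue bars to the left for lower. Counts against 2 months are 4 higher and 3 lower at 9 months, 2 and 3 at 15 months, 26 and 15 at 24 months and 31 and 17 at 30 months, and 2 of the 3 consecutive pairs have none.

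At 9 against 2 months, the earliest adult interval, mir-296 already stood at 19.8% of its young level. mir-296 lies on chromosome 2 (174267047 to 174267125, minus strand of GRCm38), within the imprinted Gnas region, and the annotation places no other gene across it on that strand. Its mean level was 96.6 ± 11.9 CPM at 2 months and 19.1 ± 4.69 CPM at 9 months (SD, n = 5 each), and its log2 change was −2.34 (SE 0.25, adjusted p = 5.25e-07). mir-298, which lies beside it (174267504 to 174267585) and was chosen after its value was seen, fell from 7.69 ± 0.884 to 1.89 ± 0.544 CPM, a log2 change of −2.01 (SE 0.32, adjusted p = 2.73e-04). mir-31, known from T cells among other types, fell by 1.18 on the log2 scale (SE 0.29, adjusted p = 0.0266). Higher at 9 months were mir-223 by 0.97 (SE 0.17, adjusted p = 9.24e-04), from 58.2 ± 2.85 to 114 ± 26.6 CPM, and mir-10a of the Hoxb gene cluster by 0.78 (SE 0.18, adjusted p = 0.0202). mir-23a by 0.65 (SE 0.16, adjusted p = 0.0341) and mir-203 by 0.57 (SE 0.15, adjusted p = 0.0457) complete the 7 changed precursors. All 5 libraries of 9 months lay beyond the 2-month mean for each of the 6 that the rule names. Of the 22 lists, myeloid and inflammation were higher (camera adjusted p = 7.96e-04 and 0.0126, or adjusted p = 0.0337 for both with an estimated correlation), with 2 of 8 and 1 of 9 members up over all precursors and 3 and 1 adjusted over the list alone. The muscle list, 3 tested members of which 0 passed and 1 passed adjusted over the list alone, was lower (adjusted p = 0.0402, but adjusted p = 0.204 with an estimated correlation), and did not pass without 2 months replicate 2 or 9 months replicate 3 or 4 (adjusted p = 0.150, 0.0814 and 0.0527). Its members mir-133a-1 and mir-133a-2 are copies of 1 microRNA and may share reads. The count of 7 was 4 with upper quartile scaling, with lane in the fit or with thinned libraries, and 3 without 2 months replicate 3, 4 or 5 or 9 months replicate 3. Without 9 months replicate 4 it was 4. Of the named calls, that of mir-203 ended in 16 of 25 alternatives, mir-23a in 12, mir-31 in 9 and mir-10a in 6, with adjusted p up to 0.377, 0.297, 0.196 and 0.110.

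At 15 against 2 months 5 precursors passed, 2 higher and 3 lower. mir-296 stood at 15.9 ± 4.88 CPM (SD, n = 5), a log2 change of −2.60 (SE 0.25, adjusted p = 7.51e-08), and mir-298 changed by −2.08 (SE 0.32). mir-211, known from pigment cells, changed by −1.78 (SE 0.44, adjusted p = 0.0341), but its level of 1.44 CPM at 2 months is near the detection floor. mir-10a rose by 1.02 log2 units (SE 0.18, adjusted p = 0.00110), from 1162 ± 179 to 2351 ± 940 CPM, and mir-203 rose by 0.60 (SE 0.15, adjusted p = 0.0341). mir-298 and mir-211 were chosen after their values were seen. The myeloid, inflammation and Sfmbt2 lists were higher (camera adjusted p = 0.00160, 0.0125 and 0.0113), with 0 of their 8, 9 and 17 members past the threshold over all precursors and likewise adjusted over the list alone. Most of the 17 Sfmbt2 members are copies of mir-669a and may share reads. Apart from mir-467d, the 17 average 0.335 to 0.839 CPM, around the floor of 0.614 CPM in the smallest library. With an estimated correlation the myeloid and inflammation lists kept an adjusted p = 0.0444 each and the Sfmbt2 list had an adjusted p = 0.690. Without 15 months replicate 3 neither the inflammation nor the Sfmbt2 list passed (adjusted p = 0.0545 and 0.270), nor did the latter without 2 months replicate 1 (adjusted p = 0.192). The count of 5 was 3 with library totals, with a filter of 10 CPM, with limma-voom, with lane in the fit, without the lane 3 libraries or with thinned libraries, and 2 in a fit of the 10 compared libraries alone. It was also 3 without 2 months replicate 1, 2 or 4 or 15 months replicate 2, 3, 4 or 5, and the call of mir-203 ended in 17 of 25 alternatives, with adjusted p up to 0.430.

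At 24 against 2 months 41 precursors passed, 26 higher and 15 lower. The largest rises among precursors of at least 10 CPM were those of mir-203 by 1.42 log2 units (SE 0.15, adjusted p = 2.62e-07), from 7.96 ± 0.702 to 21.2 ± 3.71 CPM, and mir-223 by 1.19 (SE 0.17, adjusted p = 3.02e-05), from 58.2 ± 2.85 to 133 ± 22.6 CPM (SD, n = 5 each). mir-23a rose by 1.06 (SE 0.17) and mir-27a by 1.01 (SE 0.19), from 61.3 ± 10.6 to 123 ± 31.7 CPM. These belong to 1 cluster with mir-24-2 on chromosome 8 (84208518 to 84208921), and mir-24-2 rose by 0.41 (SE 0.10, adjusted p = 0.0110). mir-296 stood at 7.74% of its young level (log2 change −3.69, SE 0.27, adjusted p = 1.50e-10). mir-144 changed by −1.06 (SE 0.35, adjusted p = 0.0486), mir-98 by −0.95 (SE 0.31, adjusted p = 0.0472) and mir-8114 by −0.60 (SE 0.16, adjusted p = 0.0146). All 5 libraries of 24 months lay beyond the 2-month mean for each of these, mir-24-2 aside, for which this was not counted. mir-451a, the most abundant red cell microRNA beside mir-486a, fell by 0.44 log2 units (SE 0.14, adjusted p = 0.0375) from 94620 ± 14550 to 69650 CPM, a call chosen for mention after its value was seen. That fall depends on the scaling, with −0.07 (adjusted p = 0.638) under library totals and −0.36 (adjusted p = 0.248) under upper quartile factors, and the call ended in 19 of 25 alternatives, among them each of the 10 fits without 1 library. The calls of mir-144 and mir-98 ended in 18 of 25 alternatives each, with adjusted p up to 0.263 and 0.280, and that of mir-8114 in 7, with a log2 change down to −0.24. The count was 24 with upper quartile scaling, without a filter or with a filter of 10 CPM, and its split was 69 higher and 3 lower with library totals and 21 higher and 3 lower with upper quartile scaling, against 26 and 15.

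Myeloid microRNAs were higher at 24 months, with 6 of 8 members up over all precursors and 6 adjusted over the list alone (camera adjusted p = 7.46e-05, and adjusted p = 0.0154 with an estimated correlation). The inflammation list was higher (adjusted p = 0.00596, and adjusted p = 0.0204 with an estimated correlation), with 2 of 9 members up by either adjustment, both of them myeloid list members. The let-7 list was lower (adjusted p = 0.0147, but adjusted p = 0.897 with an estimated correlation), with mir-98 alone of 13 members past the threshold and 3 adjusted over the list alone. Without 24 months replicate 2, which was low in let-7f-1 and let-7g, the let-7 list did not pass (adjusted p = 0.123). The Sfmbt2 list, a cluster of low-abundance repeat-like hairpins, was higher (adjusted p = 0.0360, but adjusted p = 0.799 with an estimated correlation), with 1 of 17 members up by either adjustment. It did not pass without 2 months replicate 1 or 24 months replicate 1 or 3 (adjusted p = 0.0750, 0.204 and 0.0924). With library totals 5 of the 13 let-7 members had values above 0, against 0 in the main scaling and 1 with upper quartile scaling.

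At 30 against 2 months, the widest interval, 48 precursors passed, 31 higher and 17 lower, of which 20 and 9 had at least 10 CPM at either age. Counting precursors with near-identical counts or overlapping hairpins once left 45. mir-203 (chromosome 12, 112130880 to 112130955, intergenic) rose 3.17-fold, from 7.96 ± 0.702 to 25.2 ± 2.87 CPM (log2 change 1.66, SE 0.15, adjusted p = 1.25e-08). mir-223 (chromosome X, 96242817 to 96242926, in an exon of the antisense transcript F630028O10Rik) rose 2.72-fold, from 58.2 ± 2.85 to 158 ± 44.1 CPM (log2 change 1.44, SE 0.17, adjusted p = 1.65e-06). mir-182, which forms a cluster with mir-183 and mir-96 and is named in red cell precursors, rose from 40.2 ± 2.67 to 108 ± 59.1 CPM (log2 change 1.42, SE 0.32, adjusted p = 0.00652). mir-10a (chromosome 11, 96317165 to 96317274, intergenic) rose from 1162 ± 179 to 2695 ± 353 CPM (log2 change 1.21, SE 0.18, adjusted p = 4.90e-05), the largest gain in CPM among the 10 named rises. mir-335, in an intron of the imprinted gene Mest, rose from 5.87 ± 1.25 to 12.3 ± 3.21 CPM (log2 change 1.07, SE 0.21, adjusted p = 0.00161). mir-23a rose from 40.3 ± 5.18 to 75.3 ± 18.5 CPM (log2 change 0.90, SE 0.17, adjusted p = 6.58e-04). mir-99b and mir-125a, which lie together in the Spaca6 region, rose by 0.95 (SE 0.28) and 0.76 (SE 0.25), mir-146b by 0.70 (SE 0.22) and mir-339 by 0.69 (SE 0.22). The n is 5 for each mean.

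The deepest fall at 30 months was again that of mir-296, to 6.43 ± 0.633 CPM or 6.66% of its young level (log2 change −3.91, SE 0.27, adjusted p = 6.49e-11). Apart from it, 8 precursors of at least 10 CPM at 2 months were lower. Among them 4 belong to the let-7 family, which is known for rising with cell differentiation. let-7f-1 fell from 1692 ± 419 to 675 ± 297 CPM (log2 change −1.33, SE 0.36, adjusted p = 0.0178), and let-7f-2, which shares its reads, changed by −1.31 (SE 0.36). mir-98 fell from 70.9 ± 12.2 to 28.8 ± 10.4 CPM (log2 change −1.30, SE 0.31, adjusted p = 0.00810) and let-7g from 555 ± 127 to 253 ± 115 CPM (log2 change −1.13, SE 0.37, adjusted p = 0.0412). mir-144, which shares a cluster with mir-451a on chromosome 11 (78073005 to 78073241), fell from 1193 ± 217 to 450 ± 258 CPM (log2 change −1.41, SE 0.35, adjusted p = 0.0101). mir-126a, an endothelial microRNA of the Egfl7 gene, fell from 12.9 ± 1.77 to 5.05 ± 2.05 CPM (log2 change −1.35, SE 0.34), mir-32, in an intron of Tmem245, from 10.6 ± 2.62 to 3.25 ± 2.09 CPM (log2 change −1.70, SE 0.45) and mir-26b, in an intron of Ctdsp1, from 826 ± 212 to 416 ± 153 CPM (log2 change −0.99, SE 0.32). All 5 old libraries lay below the 2-month mean for each fall, and 5 of 5 lay above it for each rise except mir-99b, mir-125a and mir-339, with 4 of 5. Below 10 CPM and chosen after their values were seen, mir-298 changed by −2.67 (SE 0.36), mir-211 by −3.30 (SE 0.61) and mir-708 by 2.46 (SE 0.75). The average log2 CPM was −0.518 for mir-211 and −0.623 for mir-708, near the floor of 0.614 CPM in the smallest library. Over all tested precursors, 36 or 10.7% had groups without overlap, where chance gives 0.79%.

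**Figure D2:**
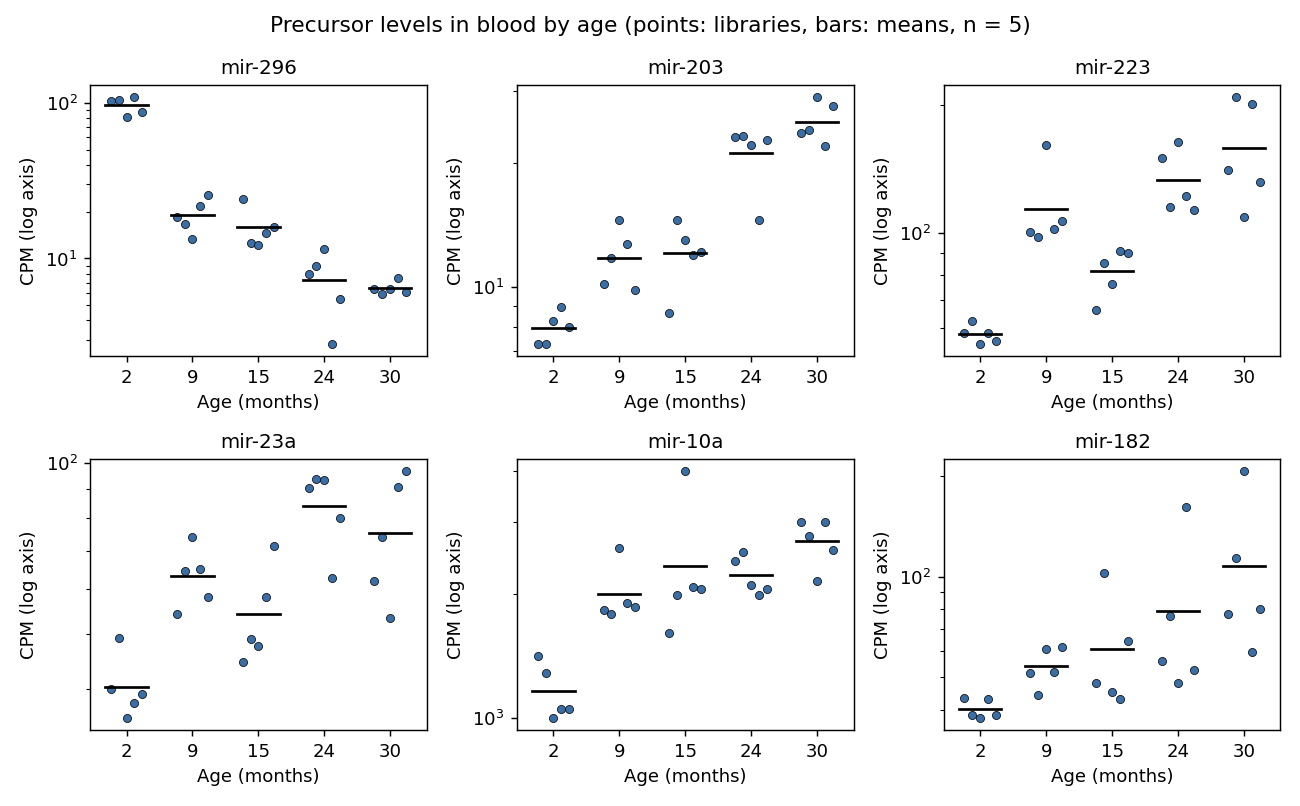
Level of 6 precursors in CPM on a log axis (vertical) against age in months (horizontal), with 1 point per library and a bar at the mean of 5. mir-296 drops from 96.6 CPM at 2 months to 19.1 CPM at 9 months and 6.43 CPM at 30 months, while mir-203 stands at 11.8 and 12.1 CPM at 9 and 15 months and at 21.2 and 25.2 CPM at 24 and 30 months.

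**Figure D3:**
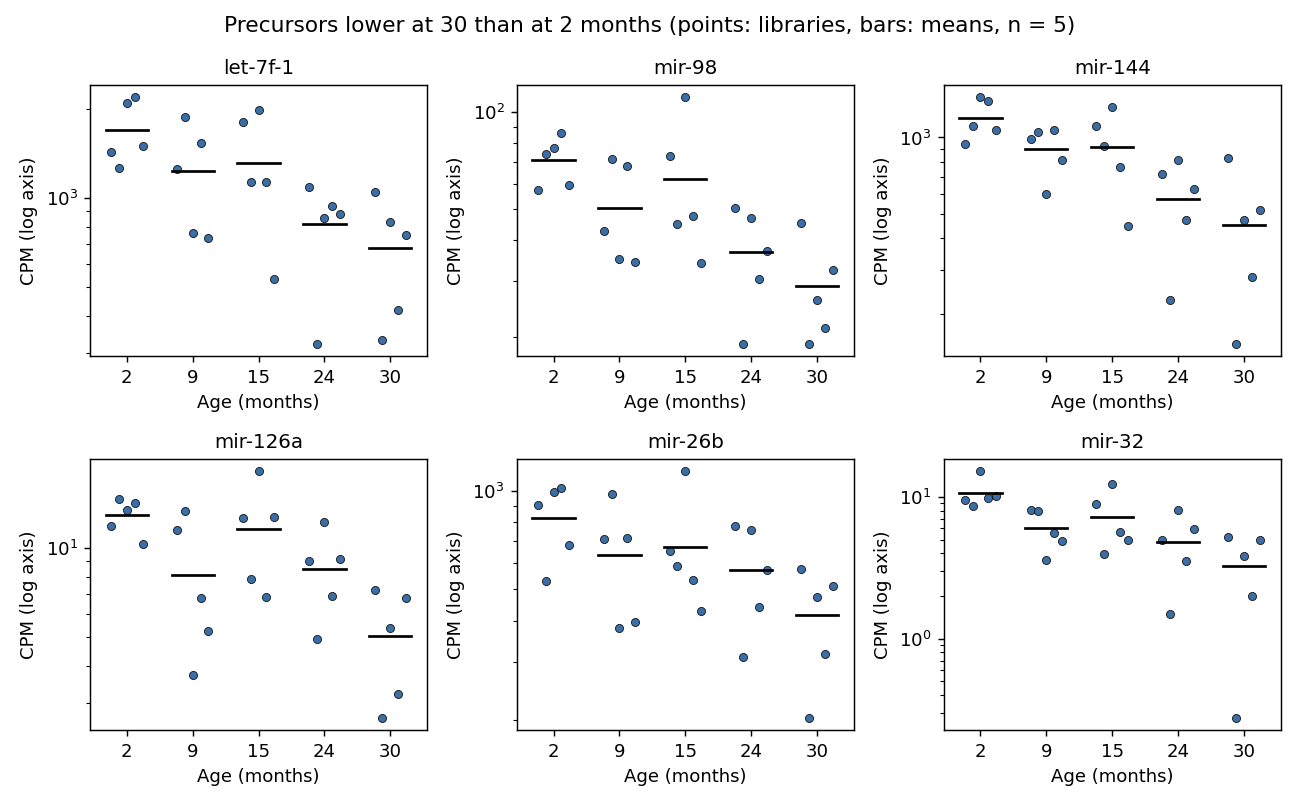
Level of 6 of the precursors lower at 30 than at 2 months, in CPM on a log axis (vertical) against age in months (horizontal), with 1 point per library and a bar at the mean of 5. The mean of let-7f-1 is 1692 CPM at 2 months and 675 CPM at 30 months, and libraries within each later age differ widely.

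Of the alternatives to the 30 against 2 months fit, none ended the calls of mir-203, mir-223, mir-182, mir-10a, mir-335, mir-23a, mir-296 and mir-98. The calls of mir-26b ended in 14 of 25, of mir-125a in 12, and of mir-339 and let-7g in 11 each. Those of mir-146b ended in 4, of mir-99b in 3 and of mir-32 in 1, those of let-7f-1, let-7f-2 and mir-144 ended with library totals and without a filter, and that of mir-126a with library totals. The count was 15 without a filter, 30 in a fit of the 10 compared libraries alone and 32 without 2 months replicate 3, and its split was 51 higher and 6 lower with library totals.

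Among the lists at 30 against 2 months, myeloid microRNAs were higher. Up were 5 of 8 members, mir-223, mir-23a, mir-146b, mir-27a (log2 change 0.58, SE 0.19) and mir-24-2 (log2 change 0.43, SE 0.10), and 6 passed adjusted over the list alone. mir-23a, mir-27a and mir-24-2 lie in 1 cluster, so their rises need not be independent, and mir-24-1 is a copy of mir-24-2. mir-22 and mir-21a were the most abundant members, at means of 35958 and 5889 CPM over all libraries. mir-24-1, mir-21a and mir-22 had log2 changes of 0.30, −0.14 and −0.03. The median was 0.51 log2 units and camera gave an adjusted p = 0.00105, with an adjusted p = 0.0429 with an estimated correlation. The inflammation list was higher (adjusted p = 0.0119, and adjusted p = 0.0429 with an estimated correlation) through mir-223, mir-132 (log2 change 0.50, SE 0.14) and mir-146b of 9 members, or 6 adjusted over the list alone. mir-146a, at 1.15 (SE 0.40, adjusted p = 0.0519), and mir-155, at 0.97 (SE 0.43), did not pass, though mir-146a passed in 10 of 25 alternatives. The let-7 list was lower (adjusted p = 0.00397, but adjusted p = 0.880 with an estimated correlation), with let-7f-1, let-7f-2, let-7g and mir-98 down of 13 members, 6 adjusted over the list alone and a median of −0.63. With library totals 4 of the 13 members had values above 0, against 0 in the other scalings. By fry, which asks whether members move one way, the myeloid list had an adjusted p = 2.23e-06, inflammation 2.73e-05 and let-7 0.142.

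The remaining lists did not pass at 30 against 2 months. Of 9 tested erythroid members mir-182 and mir-183 were up and mir-144 was down (adjusted p = 0.670). In the platelet and endothelial list mir-10a was up and mir-126a and mir-199a-1 were down of 7 (adjusted p = 0.552). Of 12 lymphoid members mir-28a was up at 0.67 log2 units (SE 0.16, adjusted p = 0.784 for the list), and mir-150, a marker of mature lymphocytes, had a log2 change of −0.31 (SE 0.44). Of 5 epithelial members mir-203 was up and mir-205 down (adjusted p = 0.763), and mir-200c, another epithelial microRNA, had a log2 change of −0.47 (SE 0.21), so that mir-203 did not move with them. In the list of miR-99 and miR-125 clusters mir-99b and mir-125a were up of 6 and in the Sfmbt2 list mir-467d of 17, with adjusted p = 0.760 and 0.288. No member passed of 3 liver (mir-192 at 0.49, adjusted p = 0.0581), 3 muscle, 9 brain, 4 smooth muscle and fibroblast, 4 p53 or senescence, 8 miR-17-92, 5 miR-106a-363, 3 miR-106b-25, 8 miR-15/16, 4 miR-29, 7 miR-30, 6 miR-181 and 9 Dlk1-Dio3 members. The muscle members mir-133a-1 and mir-133a-2 had log2 changes of −1.73 (SE 0.73) and −1.69 (SE 0.73), and all 3 passed adjusted over the list alone, as did 4 epithelial members downward, 2 miR-30 members downward and 1 liver member upward. mir-133a-1 and mir-133a-2 are copies of 1 microRNA, at means of 25.2 and 25.4 CPM, and may share reads. The other tested muscle member averaged 0.877 CPM, near the floor. Adjusted over the list alone 2 erythroid members rose and 1 fell, 2 lymphoid, 2 of miR-99 and miR-125 and 1 platelet and endothelial member rose and 2 of the latter fell. 1 epithelial member rose by that adjustment, and the other lists had 0. Too small to test, the list of miR-183, miR-96 and miR-182 had 2 of 2 tested members up, that of miR-221 and miR-222 1 of 2 (mir-222 at 0.31) and the pancreas list 0 of 1.

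**Figure D4:**
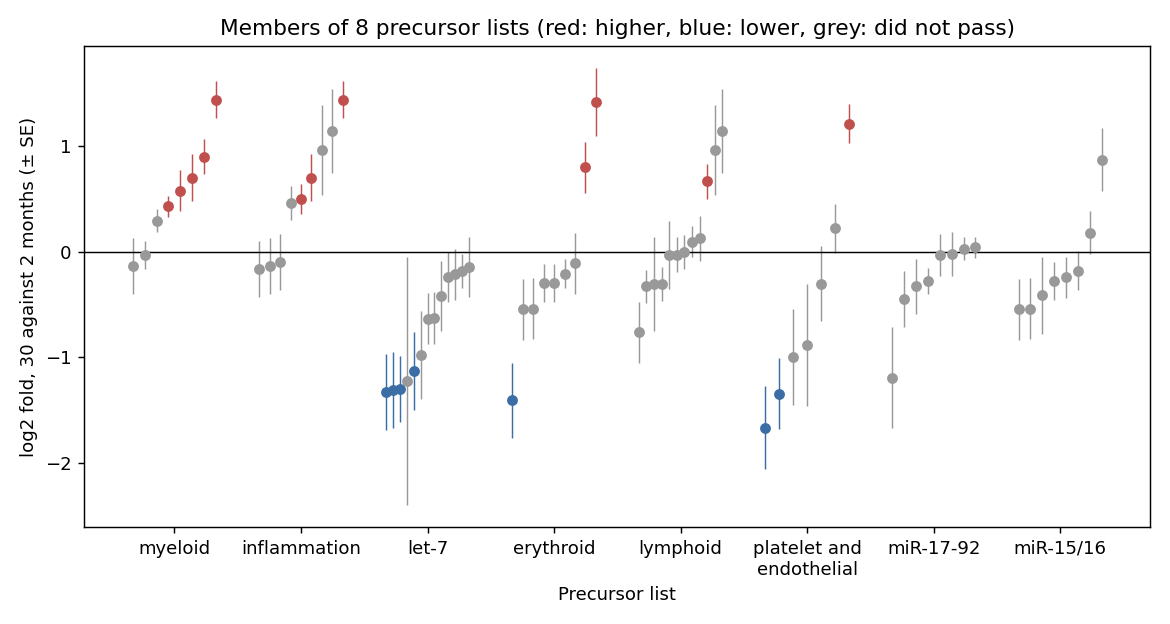
Log2 change at 30 against 2 months (vertical axis, error bars 1 SE) of each tested member of 8 precursor lists (horizontal axis), in red where higher, blue where lower and grey where the member did not pass. Myeloid members run from −0.14 to 1.44 with 5 of 8 passing upward, and let-7 members lie below 0 with 4 of 13 passing, though 4 of the 13 lie above 0 when libraries are scaled by their totals.

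Consecutive ages were compared to ask between which ages the levels moved. Between 9 and 15 months 0 precursors passed with edgeR, 7 had an unadjusted p under 0.05, and DESeq2 and limma-voom also called 0. Between 24 and 30 months the counts were 0 with edgeR, 13 unadjusted, and 0 with DESeq2 and limma-voom. Between 15 and 24 months 7 passed. Higher at 24 months were mir-203 by 0.81 log2 units (SE 0.15, adjusted p = 0.00417), mir-27a by 0.76 (SE 0.19), mir-223 by 0.70 (SE 0.17), mir-28a, in an intron of Lpp, by 0.66 (SE 0.16) and mir-23a by 0.64 (SE 0.16). mir-3065, at 0.78 (SE 0.20), was chosen after its value was seen. Lower was mir-296, by −1.09 (SE 0.25, adjusted p = 0.0302). mir-203, mir-27a, mir-223, mir-28a and mir-296 were beyond the 15-month mean in 5 of 5 libraries of 24 months. The count of 7 is fragile: it was 0 in a fit of the 10 compared libraries alone (24 with an unadjusted p under 0.05), 1 without a filter, 2 with upper quartile scaling (2 higher, 0 lower) or without abundant precursors in the scaling (1 higher, 1 lower), 12 with DESeq2 and 16 with library totals (16 higher, 0 lower). It was 1 without 15 months replicate 1 or 4 or 24 months replicate 1 or 5, 2 without 15 months replicate 3, and 4 without 15 months replicate 2 or 5 or 24 months replicate 3. Lists were not compared between consecutive ages.

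The log2 changes of 24 and 30 months against 2 months correlated across the tested precursors, which are not independent replicates, at r = 0.890. Both use the same 2-month libraries, and unchanged groups simulated against them gave a mean r of 0.470. The covariance was 0.341 against 0.0479 in the simulation. Precursors were drawn independently there, so variation that precursors share between libraries is absent and the simulated values are not a full reference. With the 2-month libraries split between the comparisons, r averaged 0.712 and ranged from 0.522 to 0.797. Called in both were 20 precursors upward and 8 downward, where independent lists would share 2.38 and 0.754, and 0 had opposite directions. The changes of 9 months against 2 and of 30 months against 24, which share no library, correlated at 0.121, and those of 9 against 2 and of 24 against 15 at 0.449.

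Library composition also moved with age. The total count fell with age (Pearson r = −0.595 over 25 libraries, permutation p = 0.00170, adjusted over 6 measures p = 0.00394, Spearman rho = −0.577 with permutation p = 0.00316). Without the 2 libraries farthest from the median total r was −0.539 and within lanes −0.60, but without the 30-month group r was −0.333. The log2 ratio of mir-451a to mir-23a was 11.2 ± 0.167 at 2 months, 10.5 ± 0.277 at 9, 10.6 ± 0.291 at 15, 9.70 ± 0.161 at 24 and 10.1 ± 0.248 at 30 months (SD, n = 5 each). It fell with age at r = −0.796 (permutation p = 1e-05, the smallest these can give, adjusted p = 6e-05, rho = −0.769 with permutation p = 1e-05), −0.784 without the 2 farthest and −0.801 within lanes. mir-23a, its denominator, is one of the myeloid precursors that rose. The number of precursors detected after thinning to 1 total was higher with age at r = 0.585 (permutation p = 0.00197, adjusted p = 0.00394, rho = 0.563 with permutation p = 0.00386, 0.527 without the 2 farthest, 0.669 within lanes), from 466 ± 12.3 at 2 months to 491 ± 10.6 at 30 months. The counts left for rarer precursors still differed after thinning, as the mean TMM factors of 0.892 and 1.06 show. The erythroid share had r = −0.391 (permutation p = 0.0543, adjusted p = 0.0815, rho = −0.377 with permutation p = 0.0662, −0.419 without the 2 farthest), which did not pass pooled, and −0.584 within lanes (permutation p = 0.00898), which did. The shares of the most abundant precursor (r = −0.243, adjusted permutation p = 0.241, rho = −0.231) and of the 10 most abundant (r = −0.269, adjusted permutation p = 0.230, rho = −0.239) did not pass. At 30 against 2 months the exact permutation p was 0.00794 for the total and for the ratio (0.0238 adjusted), 0.0238 for precursors detected (0.0476 adjusted) and 0.0556 for the erythroid share (0.0833 adjusted).

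**Figure D5:**
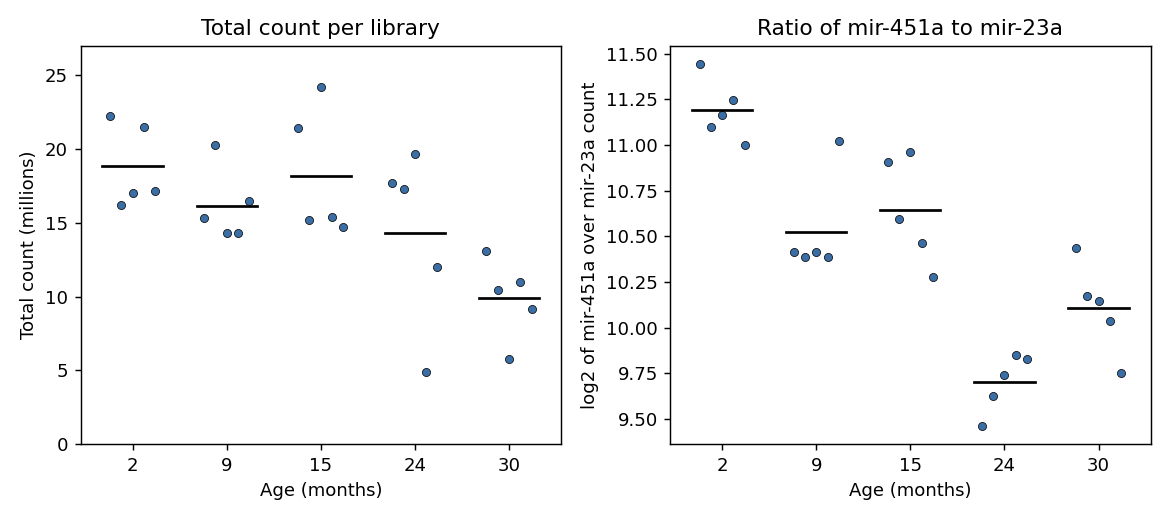
Total count in M (left) and log2 ratio of mir-451a to mir-23a counts (right) on the vertical axes against age in months on the horizontal axes, with 1 point per library and a bar at the mean of 5. The mean total is 18.84 M at 2 months and 9.888 M at 30 months, and the mean ratio is 11.2 at 2 months and 9.70 at 24 months.

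The spread between animals of one age, over 87 precursors of at least 100 CPM, averaged 0.281 ± 0.0871 log2 units at 2 months and 0.387 ± 0.118 at 30 months (SD, n = 5 each), and this difference of 0.106 did not pass (exact permutation p = 0.159). Over all 25 libraries the spread had r = 0.396 with age (permutation p = 0.0496, rho = 0.412 with permutation p = 0.0432) and 0.423 within lanes (permutation p = 0.0852). Without 24 months replicate 2 and 30 months replicate 2, the 2 farthest, r was 0.27. With library totals the difference at 30 months was 0.139 and passed (exact permutation p = 0.0476), but r was 0.355 and did not (permutation p = 0.0817). Over precursors of at least 1000 CPM neither passed, with a difference of 0.0695 (exact permutation p = 0.373) and r = 0.234 (permutation p = 0.261).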

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

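Among the tests in this part, those of depth, lane, GC content, erythroid share and the axis as the whole cause were chosen only after the result was seen, as were the settings with lane, thinned libraries and a GC offset, and the minimum of 20 counts in the test of a primary transcript was set after its value was seen.

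Single libraries stood far from the other 4 of their age in 30 groups of values, or 8.96% of those examined, where chance gives about 1 in 20. The values are CPM, each with the range of the other 4 libraries. In 24 months replicate 2, 8 precursors were low: let-7f-1 at 320.7 (852 to 1092), let-7g at 126.3 (301 to 415), mir-16-1 at 7659 (13720 to 15850), mir-130a at 115.6 (187 to 218), mir-17 at 101.6 (196 to 250), mir-93 at 1072 (2462 to 3039), mir-29a at 500.4 (636 to 671) and mir-181a-2 at 531.3 (693 to 747). In 30 months replicate 3, mir-99b at 24.52 (68.4 to 79.8), mir-125a at 28.49 (61.1 to 80.3), mir-128-1 at 351.3 (496 to 513) and mir-128-2 at 300.8 (403 to 440) were low. In 9 months replicate 3, mir-223 at 161 (98.1 to 107), mir-10a at 2591 (1796 to 1912) and mir-132 at 22.31 (16.8 to 18.2) were high. In 2 months replicate 1, mir-92a-1 at 31680 (24540 to 26100), mir-92a-2 at 10650 (8015 to 8199) and mir-194-2 at 135.4 (98.1 to 107) were high.

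In 9 months replicate 5, mir-146a was low at 8.034 (23.8 to 36.5) and the log2 ratio of mir-451a to mir-23a was high at 11.02 (10.39 to 10.42). In 9 months replicate 1, mir-128-1 at 350.5 (436 to 467) and mir-128-2 at 279 (355 to 382) were low. mir-10b was high in 15 months replicate 2 at 395.3 (109 to 143) and in 24 months replicate 4 at 317.4 (74.4 to 101), where mir-203 was low at 14.6 (22.1 to 23.3). mir-10a was high in 15 months replicate 3 at 3996 (1608 to 2091). In 15 months replicate 5, mir-99b was high at 82.93 (35.0 to 42.1) and mir-29c low at 7.429 (17.9 to 21.2). mir-18a was high in 24 months replicate 1 at 81.04 (63.9 to 66.1) and mir-30a in 30 months replicate 2 at 7930 (6630 to 6882).

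mir-296 and its neighbour mir-298 were lower at 30 months, by −3.29 log2 units on average. Lane is argued against, with −3.33 when it was in the fit, and so is a linear effect of hairpin GC content, with −3.31 after a GC offset. The GC content of the mature sequence was not tested. Libraries thinned to the smallest total gave −3.18, so the calls do not rest on unequal totals. Thinning keeps expected shares, so it cannot decide whether what lowered the totals also lowered these precursors. Each setting had both precursors past the threshold and an SE near 0.30. A fall of their shared primary transcript stays open. The deviations of the pair from their age means correlated at r = 0.0013 over 25 libraries (permutation p = 0.993, rho = 0.173 with permutation p = 0.420, r = 0.141 without the 2 farthest). A correlation near 0 had been set beforehand to count against it, but mir-298 had as few as 6 counts in a library, so counting noise could hide a shared variation, and age itself remains an untested biological explanation.

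let-7f-1, let-7f-2, let-7g, mir-98, mir-26b, mir-32, mir-144 and mir-126a were lower at 30 months, with a median of −1.32 log2 units. Thinned libraries gave −1.32 with all 8 past the threshold, so the calls do not rest on unequal totals. Thinning keeps expected shares and cannot decide more about depth. A GC offset gave −1.30 with 7 of 8, which argues against a linear effect of hairpin GC content, with the mature sequence untested. There mir-26b lost its call (adjusted p = 0.0545), with an SE of 0.35 after 0.32 and a log2 change of −1.004 after −0.99. An axis on which libraries of 1 age also differ could explain part of the falls: within ages it carries 42.3% of the variance of 105 precursors and correlates with the 8 at a median r of 0.848, and with it in the fit the median was −0.82, too near to −0.66, 0.5 of the full fall, at a mean SE of 0.21. Its score was −0.593 ± 1.23 at 30 and 0.56 ± 0.993 at 2 months (SD), a difference that did not pass (exact permutation p = 0.143). The axis as the whole cause is not decided. With it in the fit 8 of 8 still passed, but it is estimated from other precursors, so part of it may remain. The SE also shrank, from 0.36 to 0.15 for let-7f-1, which makes passing easier. Over all tested precursors 67 passed in that fit, 37 higher and 30 lower, against 48 without the axis. Age and RNA quality remain open as untested.

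Myeloid microRNAs were higher at 30 months, with a median of 0.51 log2 units over 8 precursors. Among them mir-23a, mir-27a and mir-24-2 lie in 1 cluster, and the most abundant, mir-22 and mir-21a, did not rise. Thinned libraries gave 0.52 and a fit with lane 0.45, each with 5 of 8 past the threshold, which argues against lane. The calls do not rest on unequal totals, but thinning keeps expected shares and cannot decide more about depth. A smaller red cell share would raise every other cell type alike, but the myeloid mean rose by 0.51 and the lymphoid mean by 0.05, a difference of 0.457 that did not pass (exact permutation p = 0.0635, n = 5 against 5). Against the mean of 143 other precursors outside both the myeloid and erythroid lists, the myeloid mean rose by 0.664 (SE 0.0643, exact permutation p = 0.00794, 5 of 5 libraries). The mean of the 143 itself changed by −0.15. This comparison largely restates the camera call, and the 143 hold red cell reads such as those of mir-451b. It therefore cannot decide whether all other cell types rose alike. A higher share of myeloid cells with age is a candidate explanation that stays open, since no cell counts are given in the sources used here.

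Random regroupings of the libraries were compared with the real ages, 100 splits each with the real one included. Chance is argued against, though 100 splits cannot exclude it, for 9 against 2 months (1 of the splits gave as many, real 7, highest other 1) and 15 against 2 (1, real 5, other 1). The same holds for 24 against 2 (1, real 41, other 20), 30 against 2 (1, real 48, other 19) and the trend (1, real 67, other 11). In 24 against 15 months (2, real 7, other 11) and any age (2, real 27, other 48) 1 other split gave more, so chance can give such counts. It is argued against less firmly there. For 15 against 9 and 30 against 24 months the real count was 0 with edgeR, so all 100 of the splits give as many (highest other 2) and they decide nothing about chance. There 7 and 13 had an unadjusted p under 0.05 and DESeq2 and limma-voom called 0.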

How the results depend on the processing

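Settings with lane, without the lane 3 libraries, without libraries under 6 M counts, with thinned libraries, with 1 precursor per read unit and with a GC offset were chosen only after seeing the data. No paired analysis was possible because replicate numbers pair no animals.

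No named precursor or list changed its direction past a threshold in any alternative. Of 1522 values of named precursors under the alternatives other than leaving out a library, 1361 stayed on their side of the threshold, 128 lost it and 33 gained it. For lists 962 of 980 stayed, 12 lost and 6 gained it. With single libraries left out, 1102 of 1250 values of precursors stayed, 135 lost and 13 gained it, and for lists 2710 of 2750, 10 and 30.

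Counts of changed precursors moved by more than 1.5 times as follows, and apart from the tests with fewer libraries or more precursors the cause was not tested. With library totals, any age gave 44 (27 as reported), 15 against 2 months 3 (5), 24 against 2 months 72 (41) and 24 against 15 months 16 (7). With upper quartile factors, 9 against 2 months gave 4 (7), 24 against 2 months 24 and 24 against 15 months 2, and TMM without the most abundant precursors also gave 2 there. With no filter, any age gave 17, 24 against 2 months 24, 30 against 2 months 15 (48), 24 against 15 months 1 and the trend 39 (67). With the filter at 10 CPM, 15 against 2 months gave 3, 24 against 2 months 24 and the trend 42. limma-voom gave 3 at 15 against 2 months and DESeq2 12 at 24 against 15 months. Fits of the 10 compared libraries alone, which have fewer libraries, gave 2 at 15 against 2 months, 30 at 30 against 2 months and 0 at 24 against 15 months with edgeR, where 24 had an unadjusted p under 0.05 and DESeq2 and limma-voom on all libraries gave 12 and 7.

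With lane in the fit, any age gave 16, 9 against 2 months 4 and 15 against 2 months 3. Thinned libraries gave 4 and 3 there, and leaving out the lane 3 libraries gave 3 at 15 against 2 months. Without libraries under 6 M counts, 30 against 24 months gave 1, against 0 with edgeR as reported (13 with an unadjusted p under 0.05, DESeq2 and limma-voom 0). Without the 2-month group the trend gave 9. With an estimated correlation 2 lists passed at 24 against 2 months and 0 (camera) in the trend, where 4 and 3 had passed with the fixed correlation. The erythroid share had r = −0.58 within lanes, and the spread difference was 0.139 with library totals.

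With library totals the median log2 change of all precursors was 0.36 at 24 against 2 months, 0.23 at 24 against 15, 0.20 at 30 against 2, 0.12 at 9 against 2, 0.11 at 15 against 2 and −0.15 at 30 against 24 months, and with upper quartile factors 0.11 at 24 against 15. As reported it was −0.038 at 30 against 2 months and nearer 0 in the others. The trend had 80 higher and 9 lower with library totals (36 and 31 as reported) and 38 and 18 with upper quartile factors.

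Leaving out single libraries gave 14 to 33 for any age, 3 to 7 for 9 against 2 months, 3 to 4 for 15 against 2, 23 to 36 for 24 against 2, 32 to 49 for 30 against 2, 1 to 7 for 24 against 15 and 43 to 71 for the trend, and 0 throughout for 15 against 9 and 30 against 24 with edgeR (7 and 13 unadjusted, DESeq2 and limma-voom 0 with all libraries). Any age gave 15 without 2 months replicate 3 or 4, 14 without replicate 5 and 17 without 24 months replicate 1. The count for 24 against 2 months was 27 without 2 months replicate 5 and 23 without 24 months replicate 5, that for 30 against 2 was 32 without 2 months replicate 3, and the trend gave 43 without that library. Depth limits what can be called below about 0.614 CPM, the level of 3 counts in the smallest library.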

Other observations

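In this part the test of mir-144 against mir-451a and that of neighbours without copies were chosen only after the result was seen, as were the precursors named in the next paragraph.

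Some further precursors differed with age. mir-351 and mir-322 lie together on chromosome X in a cluster known for slowing the cell cycle. mir-351 stood at 39.95 ± 5.13 CPM at 2 months, 69.9 ± 10.2 at 24 and 63.1 ± 10.1 at 30 months (SD, n = 5 each), with log2 changes of 0.81 (SE 0.20, edgeR adjusted p = 0.0112) and 0.66 (SE 0.20, adjusted p = 0.0322). mir-322 had 0.87 (SE 0.30, edgeR adjusted p = 0.0504) at 30 months and did not pass there, but passed in 16 alternatives. mir-330, in an exon of Eml2, rose by 0.88 (SE 0.21, edgeR adjusted p = 0.00750) at 24 and 0.67 (SE 0.21, adjusted p = 0.0380) at 30 months. mir-23b, a close relative of mir-23a on chromosome 13, rose by 0.53 (SE 0.14) and 0.58 (SE 0.14). mir-484, one of the more abundant precursors at 1224 ± 211 CPM in young mice, fell by 0.46 log2 units (SE 0.15, edgeR adjusted p = 0.0486) at 24 months and had −0.31 (SE 0.15, adjusted p = 0.186) at 30 months.

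Precursors that lie close together may be made from shared transcripts and then change alike. Over 151 pairs within 10 kb on the same strand, made by 116 precursors, the median difference between the log2 changes at 30 against 2 months was 0.320, against 0.493 with the changes shuffled over precursors (0.367 to 0.648), with a 1-sided permutation p of 0.0029. Pairs with near-identical counts or overlapping hairpins were left out. Without a further 66 pairs that are copies of 1 microRNA or lie in the Sfmbt2 cluster, and so may share reads, the 85 left gave 0.320 as well (0.338 to 0.685 when shuffled, 1-sided permutation p = 0.0129). The shuffling did not match precursors by abundance or SE. Neighbours measured with less noise would also differ less, so these tests cannot decide whether transcripts are shared.

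mir-144 and mir-451a, which share a transcript on chromosome 11, moved apart. The log2 ratio of mir-144 to mir-451a was −6.31 ± 0.43 at 2 months and −7.71 ± 1.02 at 30 months (SD, n = 5 each), a change of −1.40 (exact permutation p = 0.0159). The pair was picked because mir-144 had fallen, so this restates that fall and decides nothing about its source, and mir-144 is one of the 8 precursors tied to the within-age axis described above.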
